A study of Mus musculus with 6 samples.

How the data were processed

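Total RNA of 2T3 mouse pre-osteoblasts was hybridised to 1-colour Affymetrix arrays, with 3 samples in each group. The cells had spent 3 days in static culture or in the rotating wall vessel, per the labels and the design text. The deposited table holds 1 intensity per probe set and array on a linear scale, for 45101 probe sets. The mean intensity after trimming 2% from each end was 500.0 on every deposited array, so each array had been scaled to a common target; the summary algorithm and software are not given in the sources used here. Detection calls were not used here, so no value is reported as a bound. Samples were grouped by their titles. For static 2 and static 3 the source field disagrees with the title.

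Values were transformed as log2(value + 16.6), the offset being the 20th percentile of all values, so differences of dim probe sets are understated. Array medians differed by 85.9%, above the tolerance of 10%, and quantile normalization was applied. The 64 control probe sets were left out, and so were probe sets whose mean lay below the 40th percentile, leaving 27022. The platform's probe table, with symbols updated through gene identifiers in a RefSeq gene table of assembly GRCm38.p6, gave 1 symbol to 34945 of the 45037 other probe sets and several to 932, and 9160 are unnamed here. Of the tested probe sets 23119 had 1 symbol, 618 several and 3285 none. A gene was represented by its probe set with the highest mean over the 6 arrays, giving 12554 genes. No genomic coordinates are printed, since no build is named for the deposited values.

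Rotated and static samples were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend, two-sided) and Benjamini-Hochberg adjustment at 0.05. Differences are log2 rotated over static, with limma's moderated standard error. Gene lists, 38 in number with 839 distinct genes of which 689 were tested, were tested with camera (preset inter-gene correlation 0.01), with camera with an estimated correlation and with fry, each adjusted over the lists. Camera compares a list with all other tested probe sets, while fry asks whether a list's own genes moved. Because no gene passed, the genes named are the 10 with the smallest p in each direction, up to 4 members with the smallest p in each list, and a short set of bone biology genes fixed in advance, where measured; probe sets of several genes are not named. The groups, the design, the lists, this naming rule and all alternatives except those said to be chosen later were fixed before the data were examined.

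Whether the replicate numbers pair the samples was checked from the deviations of each sample from its group mean. The correlation of deviations was 0.196, 0.313 and 0.334 for the same-numbered pairs, and between -0.19 and -0.09 for differently numbered ones. Every same-numbered pair thus deviated together, so the numbers may pair the samples. Deviations within a group cancel out, so positive values for some pairs go with negative values for others, and the check does not decide it. The labels do not say what a number stands for. All differences, standard errors and p-values come from the fit without a block unless the block is named. The fit with a replicate block is given beside calls it changes.

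Alternatives were the values as deposited, median centring, a smaller and a larger offset, no filter and a stricter filter on dim probe sets, no intensity trend, robust eBayes, array weights, the replicate block, the mean over the probe sets of a gene, and leaving out each sample in turn. Scaling and filtering used all 6 arrays before any sample was left out. Leaving out static 1 and rotated 1 together and the actin ratio as a covariate were added after the data were seen. The limma and list steps were tested on simulated data with 27022 probe sets, 3 against 3 arrays and 200 changed probe sets in each of 20 runs. They recovered 11.9% of probe sets changed 2-fold and 73.5% of those changed 4-fold with 5.8 false calls per run, and a list shifted by 0.5 (log2) was found in 20 of 20 runs by each list test. The simulated genes were independent of each other, unlike real ones.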

Results

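RNA of 2T3 cells was profiled after 3 days in static culture or in a rotating wall vessel, and the deposited signals of 6 arrays were compared. 2T3 is a clonal mouse pre-osteoblast line from the calvaria, immortalised with a viral T antigen. The rotating wall vessel is a fluid-filled chamber turned about a horizontal axis, which keeps cells suspended and serves as a ground-based model of microgravity. There were 3 static and 3 rotated samples with 1 array each, so the number of arrays limits the precision of every value. The labels do not say whether the samples came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The source field of static 2 and static 3 names simulated microgravity, against their titles, which name static culture; the titles were used. The titles of both groups begin with the letters RWV, and those of the other group name the condition only by the letter R. That letter was taken here as rotated because simulated microgravity is the other condition in the design text. The median deposited signal was between 70.0 and 130.1 per array.

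The comparison asked which transcripts differ between static culture and simulated microgravity after 3 days. At the level of gene groups, transcripts of small leucine-rich proteoglycans, fibrillar collagens, BMP and TGF-beta signalling, Wnt signalling, and MHC class I and complement stood lower in the rotated samples, and heat shock protein transcripts stood higher, as called by camera with a preset correlation between genes. With an estimated correlation 0 lists were called (smallest adjusted p 0.258). For MHC class I and complement, rotated 3 (-0.08) lay within the range of the static samples (-0.18 to 0.33). Of the 10 splits of the samples into equal groups, 5, the real one included, gave at least as many lists called by camera. Among single genes the smallest p-values in the lower direction belonged to Islr, Ccn1 and Bmp4, and in the higher direction to Col4a1, Ercc1 and Ptgs2. No single gene passed the test after adjustment over all probe sets, so the values of single genes below are given as measured differences. The mitosis list was not called, with Mki67 at 0.16 ± 0.26 and Top2a at -0.02 ± 0.20, its other probe set at 0.74 ± 0.49 (log2 rotated over static ± SE, n = 3 per group, both chosen after their values were seen).

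Of the 10 genes with the smallest p in the lower direction, Islr, a leucine-rich repeat protein of mesenchymal cells, was 6.28-fold lower in the rotated samples (log2 difference -2.65 ± 0.33, SE). Ccn1 (Cyr61), a matricellular protein, was 3.16-fold lower (-1.66 ± 0.22), and the other 3 tested probe sets of this gene were lower too. Bmp4, a bone morphogenetic protein that drives osteoblast differentiation, was 2.72-fold lower (-1.45 ± 0.21). Ccn5 (Wisp2), which lies downstream of Wnt signalling, differed by -1.52 ± 0.23. The Wnt agonist Rspo2 differed by -1.52 ± 0.26 and Fst, the activin antagonist follistatin, by -1.18 ± 0.20. Pappa2, a protease of IGF-binding proteins, stood at -2.16 ± 0.36. The cold-inducible RNA-binding protein gene Cirbp stood at -2.26 ± 0.37, the stress gene Gadd45g at -1.44 ± 0.24 and the glycogen-targeting phosphatase subunit gene Ppp1r3b at -1.75 ± 0.29. Adjusted p in limma was between 0.300 and 0.316 for these 10 genes.

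In the higher direction, Col4a1, a chain of the type IV collagen of basement membranes, was 2.91-fold higher in the rotated samples (log2 difference 1.54 ± 0.21, SE). Ptgs2, the inducible cyclooxygenase that makes prostaglandin precursors, was 2.37-fold higher (1.24 ± 0.22), and the DNA repair nuclease gene Ercc1 was 2.36-fold higher (1.24 ± 0.20). The calcium-activated potassium channel gene Kcnn4 differed by 1.91 ± 0.40, the cysteine protease inhibitor gene Cst6 by 1.65 ± 0.33 and the chaperone gene Hsph1 by 1.39 ± 0.28. Tuba4a, an alpha-tubulin, differed by 1.23 ± 0.23, the heme transporter gene Slc48a1 by 1.23 ± 0.23 and the mitochondrial import gene Timm8b by 0.93 ± 0.19. The chloride transporter gene Clcn5 stood at 1.30 ± 0.26, with 1 of its 3 other tested probe sets in the opposite direction. Adjusted p in limma ranged from 0.300 to 0.487 for these 10 genes. In all 20 genes of both directions the 3 rotated values lay entirely outside the 3 static values, which the choice by smallest p favours.

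**Figure D1:**
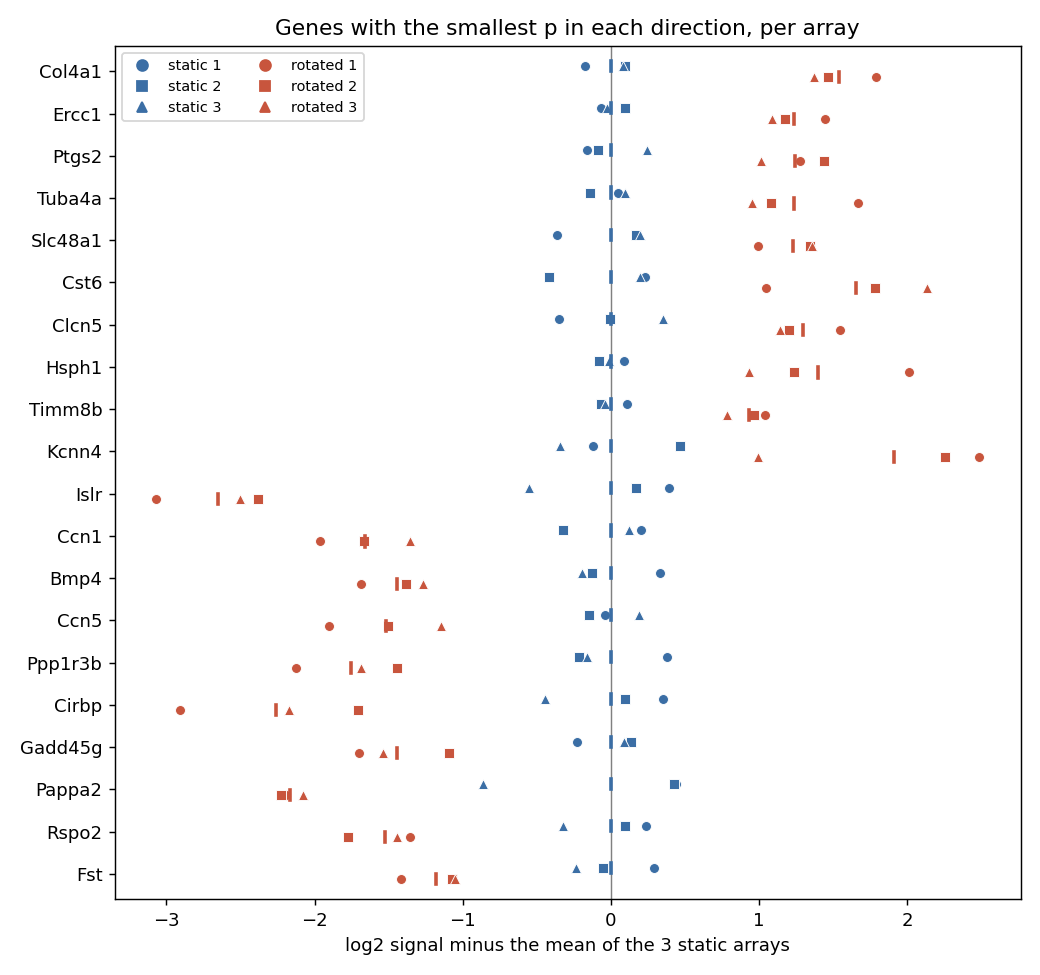
Log2 signal of the 20 genes with the smallest p in each direction, per array, relative to the mean of the 3 static arrays (horizontal axis, log2 units). Each symbol is 1 array and each vertical tick a group mean. The rotated arrays lie outside the static ones for every gene, from Kcnn4 at 1.91 to Islr at -2.65, which the choice by smallest p favours.

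At an adjusted p under 0.05 limma called 0 of 27022 probe sets, and the smallest adjusted p was 0.300. At an unadjusted p under 0.05 there were 2228 probe sets, 1173 higher and 1055 lower in the rotated samples, where 1351.1 are expected by chance. The rotated and static values did not overlap in 15.1% of probe sets, against 10% by chance if all 6 arrays are exchangeable. That share leaves a possible pairing by replicate number out of account. With the replicate number as a block, 2 probe sets passed, both lower in the rotated samples, and 3957 had an unadjusted p under 0.05. The 2 that passed are second probe sets of the proteoglycan genes Ogn (-2.09 ± 0.13, adjusted p 0.0251) and Aspn (-2.15 ± 0.14, adjusted p 0.0251). The probe sets that represent these genes, whose values are given further below, did not pass with the block. With array weights, 22 probe sets passed, 6 higher and 16 lower, among them Ccn1, Ccn5, Islr, Bmp4, Vcam1, C1s1, Col4a1 and Ercc1. The weights were 0.35, 1.01 and 3.32 for static 1, static 2 and static 3, and 0.41, 2.55 and 0.81 for rotated 1, rotated 2 and rotated 3. These calls therefore rest mostly on static 3 and rotated 2. The unadjusted count was 1091 without rotated 1 and 3362 without rotated 3.

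The actin control probe sets gave a 3' over 5' signal ratio of 3.21 in rotated 1, against 1.57 and 1.48 in rotated 2 and rotated 3 and 1.29 to 1.37 in the static samples. The same ratio of the transferrin receptor controls was 8.92 in rotated 1 and 1.62 to 3.71 on the other arrays, while that of the GAPDH controls lay between 0.748 and 0.875 on all 6 arrays. Static 1 had a 10th percentile of signal of 22.1, against 4.5 to 7.2 on the other arrays. Rotated 1 and static 1 also had the lowest mean correlation with the other arrays, 0.914 and 0.918 across probe sets, against 0.942 to 0.948.

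**Figure D2:**
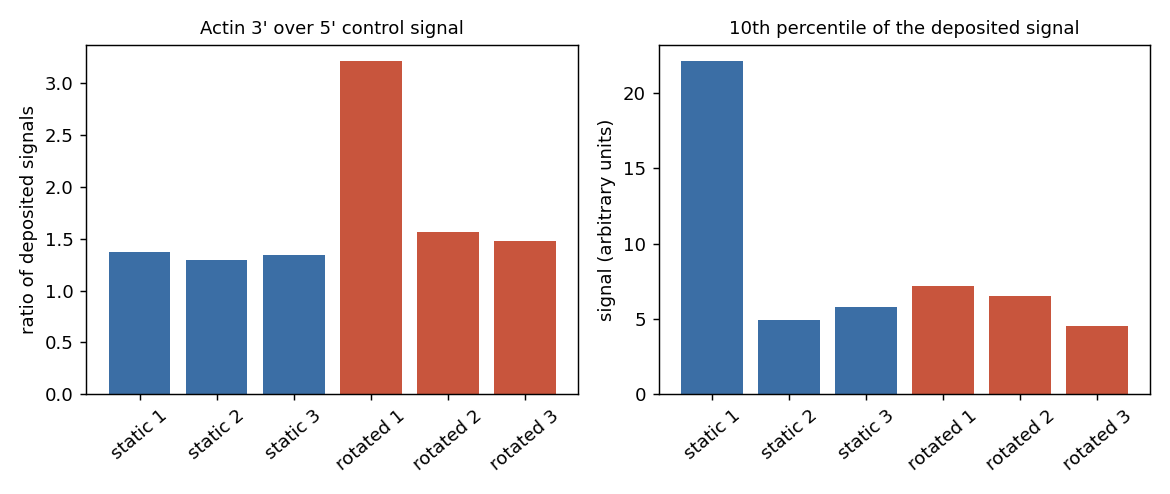
Actin control ratio (left, 3' signal over 5' signal) and 10th percentile of the deposited signal (right, arbitrary units) for each of the 6 arrays, static in blue and rotated in red. The ratio was 3.21 in rotated 1 and at most 1.57 on the other arrays; the percentile was 22.1 in static 1 and at most 7.2 on the others.

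The small leucine-rich proteoglycans, which bind collagen fibrils and growth factors in the matrix, were lower in the rotated samples for all 10 measured members, with a median log2 difference of -0.85. Adjusted over the list alone, 6 members passed, all lower, and 0 passed over all probe sets. Omd, an osteoblast proteoglycan (osteomodulin), differed by -3.27 ± 0.78, Aspn by -2.42 ± 0.62, Ogn by -1.99 ± 0.38 and Prelp by -1.21 ± 0.30. The camera test put the list below the other tested probe sets (adjusted p 4.75e-09), and adjusted p = 0.258 with an estimated correlation. The mean level of the list against the static mean was -1.68 in rotated 1, the array with the high actin ratio, and -0.92 and -1.17 in rotated 2 and rotated 3.

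Fibrillar collagen and collagen-processing genes were lower for 19 of 26 members, with a median of -0.37 (camera adjusted p 8.81e-06, and adjusted p = 0.660 with an estimated correlation). No member passed, whether adjusted over the list alone or over all probe sets. The type VI collagen genes Col6a1 and Col6a2 differed by -0.96 ± 0.26 and -0.66 ± 0.19, Col11a1 by -1.92 ± 0.53 and Col3a1 by -0.52 ± 0.17. The rotated mean of Col11a1 (5.53) lay below the filter's threshold for dim probe sets (5.96), so its difference on the offset log2 scale is not an exact fold. Col1a1, the main collagen of bone, stood at -0.79 ± 0.34. The list's mean level was -0.80 in rotated 1, with its actin ratio of 3.21, and -0.22 and -0.29 in the other rotated samples; without rotated 1 the median was -0.19, and with median centring -0.16, and the call was kept. Matrix glycoprotein and elastic fibre genes were lower for 12 of 19 members, with a median of -0.25 (camera adjusted p 0.0410, and adjusted p = 0.660 with an estimated correlation). Thbs2, an antiangiogenic matricellular protein, passed adjusted over the list alone (-1.31 ± 0.27), while the fibulin genes Fbln5 and Fbln2 stood at -0.89 ± 0.26 and -0.96 ± 0.33. The other probe set of Fbln2, a dimmer one, stood at 1.25 ± 0.41. Rotated 1 had a mean level of -0.63 for this list, against -0.19 and -0.18, and the call was lost without rotated 1 (median -0.08, adjusted p 0.155) or without static 1 (adjusted p 0.0616). Its median was -0.40 without static 2 and -0.42 without rotated 3, with the call kept. The call was also lost with the values as deposited, the stricter filter, no intensity trend, array weights, the actin covariate and both outlying arrays left out (adjusted p over all alternatives 0.0154 to 0.618). With the actin ratio as a covariate the medians were -0.10 for collagens and -0.0042 for glycoproteins.

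BMP and TGF-beta signalling genes were lower for 18 of 24 members, with a median of -0.32 (camera adjusted p 0.00161, and adjusted p = 0.462 with an estimated correlation). Bmp4 and Fst passed adjusted over the list alone, and 0 members passed over all probe sets. Id3, a direct BMP target, stood at -1.33 ± 0.48 and the BMP receptor gene Acvr1 at -0.67 ± 0.25, with 1 of its 2 other probe sets in the opposite direction. The list holds ligands and antagonists alike; follistatin is an antagonist. Its mean level was -0.61 in rotated 1, the array with the actin ratio of 3.21, and -0.29 and -0.17 in rotated 2 and rotated 3. The median was -0.15 with the actin ratio as a covariate and -0.06 without static 1 and rotated 1 together, with the call kept.

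Wnt signalling genes were lower for 15 of 23 members, with a median of -0.15 and a mean of -0.40 (camera adjusted p 0.00161, and adjusted p = 0.293 with an estimated correlation). Adjusted over the list alone 4 members passed, all lower: Ccn5, the secreted Wnt modulator Sfrp2 (-1.41 ± 0.31) and the receptor genes Fzd1 (-0.94 ± 0.22) and Fzd2 (-1.29 ± 0.34, with 1 of its 2 other probe sets in the opposite direction). The list's mean level was -0.47 in rotated 1 and -0.28 and -0.44 in rotated 2 and rotated 3. The median was -0.49 without static 2, -0.24 without static 3 and -0.31 without rotated 2, and -0.06 with median centring, with the call kept each time.

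Genes of osteoblast differentiation and mineralisation were lower for 11 of 15 members, with a median of -0.28. The list was not called (camera adjusted p 0.0752, and adjusted p = 0.660 with an estimated correlation). It was called without static 1 (median -0.49, adjusted p 0.0210), with the stricter filter on dim probe sets (0.0221) and without static 1 and rotated 1 together (0.0198), within a range of 0.0198 to 0.230 over the alternatives. The homeobox gene Dlx5 stood at -1.08 ± 0.32, Cdh11 at -0.51 ± 0.15 and Sp7, the osteoblast transcription factor osterix, at -0.84 ± 0.34. Ank, a pyrophosphate transporter, stood at 0.48 ± 0.18. Alpl, alkaline phosphatase, differed by -0.28 ± 0.47, Ibsp, bone sialoprotein, by -0.55 ± 0.47 and the parathyroid hormone receptor gene Pth1r by -0.35 ± 0.94, each within its error or close to it. The group means of these genes lay between 6.09 and 6.91, near the threshold for dim probe sets (5.96). Their differences may be understated and do not show that the genes were unchanged. The collagen-degrading protease gene Ctsk differed by 0.50 ± 0.38. Runx2, Spp1 and Bglap were not analysed here.

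Heat shock protein genes were higher for 16 of 17 members, with a median of 0.37 (camera adjusted p 3.56e-06, and adjusted p = 0.462 with an estimated correlation). Adjusted over the list alone 4 members passed, all higher, and 0 passed over all probe sets. These were Hsph1 (1.39 ± 0.28), the inducible Hspa1a (1.56 ± 0.36), the small heat shock protein gene Hspb1 (0.96 ± 0.21) and the mitochondrial co-chaperonin gene Hspe1 (0.77 ± 0.22). The mean level of the list was 0.82 in rotated 1, with its actin ratio of 3.21, and 0.48 and 0.31 in rotated 2 and rotated 3. Without rotated 1 the median was 0.21, and with the actin ratio as a covariate 0.20, with the call kept.

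**Figure D3:**
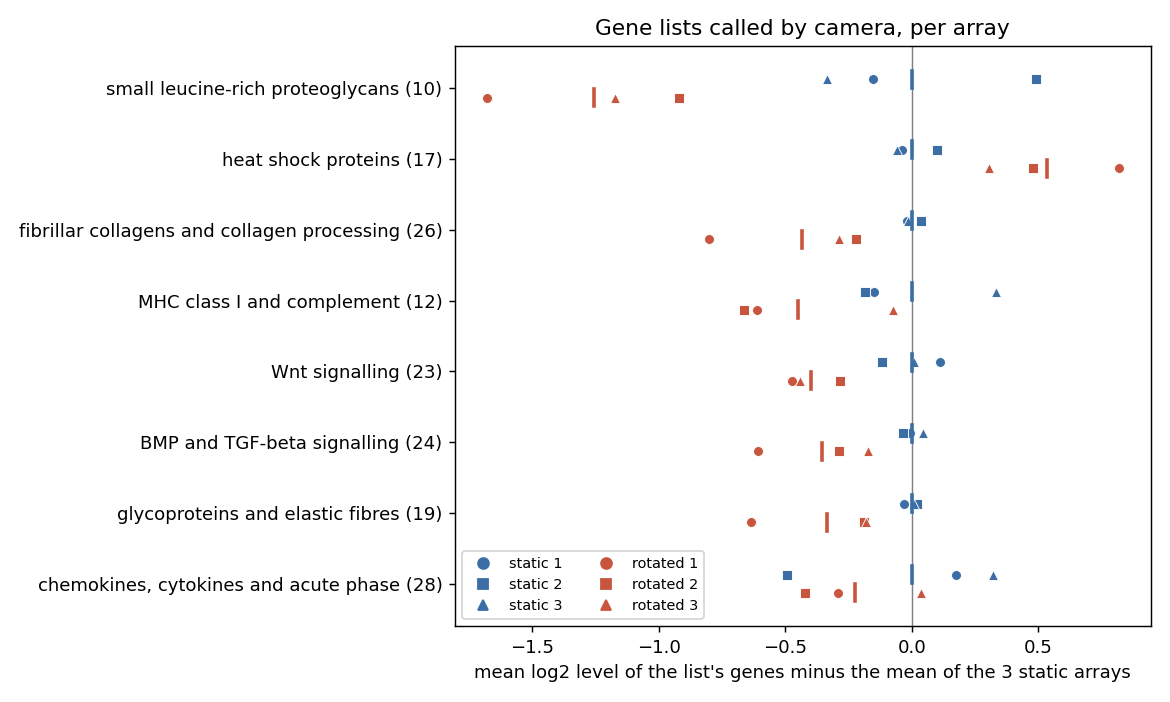
Mean log2 level of each gene list called by camera, per array, relative to the mean of the 3 static arrays (horizontal axis, log2 units; number of measured genes in brackets). Symbols are arrays and ticks group means; for small leucine-rich proteoglycans the rotated arrays lie at -1.68, -0.92 and -1.17, and for heat shock proteins at 0.82, 0.48 and 0.31.

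MHC class I and complement genes were lower for 11 of 12 members, with a median of -0.36 (camera adjusted p 0.000722, and adjusted p = 0.660 with an estimated correlation). The members that passed adjusted over the list alone, 3 in number, belong to the first complement component and its inhibitor: C1s1 (-1.18 ± 0.21), C1ra (-1.05 ± 0.24) and Serping1 (-1.04 ± 0.31). The antigen-presenting gene H2-K1 stood at -0.58 ± 0.32, with 1 of its 3 other probe sets in the opposite direction. The list's mean level was -0.61 in rotated 1, -0.66 in rotated 2 and -0.08 in rotated 3. In static 1, static 2 and static 3 it was -0.15, -0.18 and 0.33, so rotated 3 lay within the static range. The list's median was -0.15 without static 3 and -0.54 without static 1, and -0.74 with array weights, with the call kept. Chemokine, cytokine and acute phase genes were lower for 20 of 28 members, with a median of -0.19 (camera adjusted p 0.0462, and adjusted p = 0.831 with an estimated correlation). Adjusted over the list alone 1 member passed higher, Ptgs2, and 1 lower, the haptoglobin gene Hp (-1.17 ± 0.24). Cxcl12 stood at -0.42 ± 0.16 and Ccl7 at -0.81 ± 0.33. The mean level was -0.29 in rotated 1, -0.42 in rotated 2 and 0.04 in rotated 3. In static 1, static 2 and static 3 it was 0.17, -0.49 and 0.32, so all rotated samples lay within the static range. The call was lost without static 1 (adjusted p 0.215), static 3 (0.614), rotated 1 (0.0616) or rotated 2 (0.255), and the median was -0.46 without static 2, -0.38 without rotated 3, -0.12 without rotated 1 and -0.04 without static 3. It was also lost with the values as deposited (adjusted p 0.370), median centring (0.423, median -0.015), the smaller offset, either change of the filter, no intensity trend, the actin covariate and both outlying arrays left out, within a range of 5.13e-06 to 0.614 over the alternatives.

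The fry test for change in either direction does not require members to move both ways. It passed for 4 lists (adjusted p 0.00801 for each): Wnt signalling, basement membrane genes, tendon and fibroblast markers, and FGF, IGF and PDGF signalling. At an unadjusted p under 0.05 in limma, Wnt signalling had 7 members lower and 0 higher, and tendon and fibroblast markers 2 lower and 0 higher. The other lists had members on both sides, 3 higher and 2 lower for basement membrane genes and 2 each way for the growth factor list. In the basement membrane list both type IV collagen genes passed as higher adjusted over the list alone, Col4a1 (1.54 ± 0.21) and Col4a2 (0.95 ± 0.24), while the laminin-binding Nid2 passed as lower (-1.31 ± 0.25). Among tendon and fibroblast markers Tnmd (-1.69 ± 0.41) and Pdgfra (-0.76 ± 0.22, with 1 of its 2 other probe sets in the opposite direction) passed as lower, of 9 members. In the growth factor list, of 23 members, Igf2 passed as lower (-1.77 ± 0.40), and Pdgfa (0.99 ± 0.29) and the feedback inhibitor Spry4 (1.13 ± 0.42, its other probe set at -0.03 ± 0.35) were higher in value. The rotated means of Tnmd and Igf2 lay below the threshold for dim probe sets (5.96), so their differences are not exact folds. The camera test called none of the last 3 lists (adjusted p 0.836, 0.145 and 0.587). Adjusted over each list alone, further members passed in lists that camera did not call: Ccng1 higher (1.20 ± 0.26) and Gadd45g lower among p53 targets and apoptosis genes (camera adjusted p 0.288), the laminin receptor subunit gene Itga6 higher (1.26 ± 0.27) and Vcam1 lower (-1.11 ± 0.23) among integrins and adhesion genes (0.337), and the glucose transporter gene Slc2a1 higher (1.01 ± 0.22) among hypoxia response genes. So did Tuba4a among microtubule and primary cilium genes (0.629), Ptgs2 among osteoclast-regulating factors (0.587) and Ccn1 among YAP/TAZ and stretch-responsive genes (0.357, called lower without static 2 with a median of -0.07 and with the actin covariate with a median of -0.18), where Ccn2, the connective tissue growth factor gene, stood at 0.64 ± 0.54.

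Metabolic and stress lists near the threshold were hypoxia response (19 of 28 members higher, median 0.33), oxidative stress and NRF2 targets (13 of 20 higher, median 0.30) and cholesterol synthesis and uptake (15 of 19 lower, median -0.26), each with a camera adjusted p of 0.0687. These medians moved when single samples were left out. Cholesterol synthesis stood at 0.16 without static 2, 0.02 without rotated 1, -0.61 without static 1 and -0.69 without rotated 2, and was called in the latter 2 cases, without static 3 and without both outlying arrays (adjusted p over the alternatives 5.97e-05 to 0.862). Hypoxia response stood at -0.0063 without static 2 and 0.17 without rotated 2, and was called higher without static 1, static 3 or rotated 1 (5.62e-05 to 0.815). NRF2 targets stood at 0.08 without rotated 3 and 0.15 without static 1, and were called higher without static 3 or rotated 1 (3.21e-06 to 0.319). Both of these lists were also called higher on the values as deposited (adjusted p 0.00669 for hypoxia response and 0.00330 for NRF2 targets), with median centring (0.0165 for both), with no filter on dim probe sets, with array weights, with the actin covariate and without both outlying arrays. Among NRF2 targets Gclc, which makes the glutathione precursor, stood at 1.02 ± 0.25 and Nqo1 at 1.16 ± 0.41, while the extracellular peroxidase gene Gpx3 stood at -1.33 ± 0.48. With the replicate number as a block, camera called cholesterol synthesis (adjusted p 0.00127), NRF2 targets (0.0423), ribosome biogenesis (0.0112) and interferon response (0.0492), making 12 lists. With an estimated correlation and no block the adjusted p = 0.831, 0.660, 0.831 and 0.841 for these 4 lists, and 0.831 for hypoxia response. Without the block ribosome biogenesis had 15 of 20 members higher (camera adjusted p 0.0902) and interferon response 18 of 28 lower (0.145). Ribosome biogenesis was also called on the values as deposited (adjusted p 0.0256), with median centring (0.0236) and without both outlying arrays. It was called without static 1 (median 0.39) or rotated 2 (0.43) and stood at -0.02 without static 2, 0.12 without rotated 1 and 0.16 without rotated 3 (adjusted p over the alternatives 5.97e-05 to 0.884). Interferon response was called without static 2 (-0.36) or rotated 1 (-0.47) and stood at 0.10 without rotated 2, 0.01 without static 3 and -0.0037 without static 1 (2.19e-10 to 0.871). It was also called lower with array weights, with the actin covariate and without both outlying arrays. The circadian clock (12 of 16 lower, adjusted p 0.0902, Cry2 -1.05 ± 0.36), matrix proteases and inhibitors (14 of 24 lower, 0.0902, Adamts5 -1.10 ± 0.33) and immediate early genes (13 of 22 lower, 0.121, Junb -1.11 ± 0.40) were not called. Without static 2 all 3 were called lower, as were the clock without rotated 2, the proteases without rotated 1 and the immediate early genes without rotated 3. With array weights the proteases (median -0.33, adjusted p 0.00608) and the immediate early genes (-0.34, 0.00774) were called lower, and with the actin covariate the proteases (0.0260). Adjusted p over the alternatives ranged from 0.0345 to 0.829 for the clock, 0.00608 to 0.412 for the proteases and 0.000178 to 0.966 for the immediate early genes. Nor were the actin cytoskeleton and SRF targets (15 of 27 lower, 0.225), where the contractile gene Myl9 stood at -1.50 ± 0.51 and Actn1 at 0.77 ± 0.19; they were called lower without rotated 2.

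Neither list of proliferation was called. Mitosis genes were higher for 16 of 29 members, with a median of 0.06 (camera adjusted p 0.898), and DNA replication genes for 18 of 33, with a median of 0.04 (0.965). The mitosis list was called higher without static 2 (median 0.32) and with array weights (0.30), and its median was -0.15 without rotated 2, -0.07 without static 1 and -0.02 without static 3 (adjusted p over the alternatives 0.00392 to 0.898). Oxidative phosphorylation (18 of 34 higher, 0.898), the unfolded protein and amino acid response (13 of 26 higher, 0.918), fatty acid synthesis (9 of 13 lower, 0.494), Notch signalling (4 of 8 lower, 0.898) and osteocyte and ion transport genes (7 of 13 lower, 0.912) were not called either. Markers of other cell types were not called: adipocyte (7 of 9 lower, 0.240), chondrocyte (5 of 8 lower, 0.674), myogenic (5 of 7 lower, 0.377), macrophage and osteoclast (7 of 9 higher, 0.898) and endothelial (3 of 5 lower, 0.898). The sign of the median differed from that of the test or the mean for DNA replication (test lower), FGF, IGF and PDGF signalling (median 0.0027, mean -0.10, test lower), YAP/TAZ genes (median 0.07, mean -0.10, test lower) and osteocyte genes (median -0.05, mean 0.06, test lower).

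In all, camera with a preset correlation called 8 of 38 lists, 1 higher and 7 lower, against 0 with an estimated correlation and 0 by fry for change in a single direction.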

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

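The tests of rotated 1 as the whole cause, and the count of splits for the fry test, were chosen after the results were seen. Among the mouse control probe sets, which no comparison uses, the probe set for the B1 repeat had a higher signal in every rotated sample than in any static one, with a log2 difference of 0.53 (1.44-fold). It was the only 1 of 19 such probe sets with this order, which chance gives 5% of the time for each, so 1 of 19 is near the chance level. Relative to the spiked cre control on the same array the difference was 0.49 (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). The probe set was picked for its order in these same arrays, which favours such a p.

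Heat shock protein genes were higher in the rotated samples (median 0.37), with an adjusted p of 0.462 in camera with an estimated correlation. Cirbp, a transcript known to fall with warming, was lower in value. Lower RNA quality of rotated 1, with its actin ratio of 3.21, is argued against only weakly as the whole cause. The list stood at 0.31 or more above the static mean in rotated 2 and rotated 3, and at most at 0.10 in a static sample. The list was picked because it was called in these same arrays, which favours such a shift. Lower RNA quality remains open as part of the cause, since the median was 0.21 without rotated 1. All rotated samples also had a higher actin ratio than any static one. A warmer culture in the rotated vessel may also be a candidate explanation, but co-chaperone and heat shock factor target genes outside the list, chosen before their values were seen, had a median of 0.0727 with 11 of 17 higher, which does not decide it. An effect of the rotated culture itself stays open and was not tested apart from these.

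The 7 lists called lower, with 142 genes of which 105 were lower in the rotated samples, had a median of -0.33, and 0 lists were called with an estimated correlation (smallest adjusted p 0.258). The raised low-end signal of static 1 is argued against only for the pooled genes and as far as its own values go. Their median was still -0.33 (-0.325) without that sample. Taken singly, the glycoprotein and chemokine lists lost their camera call without static 1 (adjusted p 0.0616 and 0.215), with medians of -0.37 and -0.17. The share of static 1 in the common scaling stayed, since the arrays were scaled and filtered before it was left out. Lower RNA quality of rotated 1 as the whole cause is argued against only weakly, and only for the pooled genes. They stood at -0.26 or lower in rotated 2 and rotated 3, and at -0.09 in the lowest static sample. The lists were picked as lower in these same arrays, which favours such a shift. For chemokines rotated 2 (-0.42) and rotated 3 (0.04) lay within the static range (-0.49 to 0.32). For MHC class I and complement rotated 3 (-0.08) did so (-0.18 to 0.33). Rotated 2 and rotated 3 also had higher actin ratios (1.57 and 1.48) than any static sample (at most 1.37). As part of the cause, lower RNA quality cannot be told apart from the culture condition. The median was -0.22 without rotated 1, which stood lowest at -0.64. A biological difference between static and rotated culture stays open as a hypothesis.

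The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 probe sets at an adjusted p under 0.05 in limma and 2228 at an unadjusted p under 0.05, and the highest of the other splits gave 11 and 2733; 10 and 3 of the 10 splits, the real one included, gave as many. For lists called by camera the real split gave 8 and the highest other 14 (5 of 10 as many), for lists changed in either direction by fry 4 and 9 (2 of 10), and for genes changed at least 1.5-fold 0 and 2 (10 of 10). Of the 8 lists, other splits also called collagens (5 of the 9 other splits), chemokines (4), heat shock proteins (3), and small leucine-rich proteoglycans, BMP and TGF-beta, Wnt, and MHC class I and complement (2 each), and none called glycoproteins. The adjusted p was as small as the real one in 4 other splits for chemokines (smallest 7.57e-09 against 0.0462) and in 1 for MHC class I and complement (4.07e-05 against 0.000722), and in 0 for the other lists. The split with 11 probe sets and 14 lists sets static 1, static 3 and rotated 3 against static 2, rotated 1 and rotated 2, which may point to a structure of the samples other than the condition; this was not tested further. Among the 4 splits that part all 3 same-numbered pairs, the real one gave 2228 probe sets at an unadjusted p under 0.05 (3957 with the block). The others gave 288, 267 and 243 (335, 287 and 417 with the block). For lists the counts were 8 against 3, 9 and 4 (12 against 3, 10 and 7 with the block). These 4 splits are too few for a share under 0.05. The probe set counts of the others lay below the 1351.1 expected by chance, and any difference between the conditions would add to the spread within their groups. They are therefore no measure of chance, and the comparison does not decide whether the condition had an effect.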

How the results depend on the processing

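Leaving out static 1 and rotated 1 together and the actin ratio as a covariate were chosen after the data were seen. In limma 0 probe sets passed under every alternative run except array weights, with 22 (6 higher, 16 lower, 14 genes changed at least 1.5-fold), and the replicate block, with 2, both lower. At an unadjusted p under 0.05 the count of 2228 became 1357 with median centring, 5148 with array weights, 3957 with the block, 702 with the actin covariate, 1091 without rotated 1 and 3362 without rotated 3. The 8 lists became 13 with array weights, 13 with the mean over a gene's probe sets, 0 with an estimated correlation and 0 by fry; they numbered 9 to 14 on leaving out each sample (14 without static 2), 12 with the block, 12 without both outlying arrays and 11 with the actin covariate. The block added 4 lists and 2 probe sets and changed no other call. The lists for small leucine-rich proteoglycans, heat shock proteins, fibrillar collagens, BMP and TGF-beta, Wnt, and MHC class I and complement stayed called by camera under every alternative that kept 1 probe set per gene and the preset correlation, but their medians moved: with the actin covariate to -0.10 for collagens, -0.15 for BMP and TGF-beta, -0.25 for Wnt and 0.20 for heat shock proteins, and without both outlying arrays to -0.06 for BMP and TGF-beta and -0.17 for collagens. The chemokine list lost its call as deposited (adjusted p 0.370) and with median centring (0.423), and the glycoprotein list as deposited (0.0899). Under these scalings all 8 list medians kept their sign. The median of all probe sets was 0.10 with median centring, 0.03 with quantile normalization and -0.03 as deposited. Median centring put the medians of heat shock proteins at 0.67, collagens at -0.16 and Wnt at -0.06, and array weights put MHC class I and complement at -0.74. The log2 difference of Alpl ranged from -0.67 to 0.0052 and that of Pth1r from -1.30 to 0.50 on leaving out each sample, and Pth1r turned to 0.12 with array weights and 0.85 with the actin covariate; neither passed. The causes were not tested. Of 968 values of 54 named genes under alternatives, 5 reversed and 12 passed the threshold.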

Other observations

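The genes in this paragraph were chosen after their values were seen, and none passed in limma after adjustment over all probe sets (adjusted p 0.346 to 0.860). Hmox1, a heme-degrading enzyme among the NRF2 targets, differed by 0.31 ± 0.49 (log2 rotated over static ± SE, n = 3 per group, adjusted p 0.860). Met, the hepatocyte growth factor receptor, stood at 1.61 ± 0.35 and Pdgfc at 0.89 ± 0.21. The protease inhibitor gene Serpinb2 stood at 2.98 ± 0.75, with a static mean (6.18) close to the threshold for dim probe sets (5.96). Chrdl1, a secreted BMP antagonist, was 5.21-fold lower (-2.38 ± 0.42), in the same direction as Bmp4 and Fst.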
